A study of Mus musculus with 26 samples.

How the data were processed

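Gene expression was measured with an Affymetrix gene-level array on 26 samples of mouse cells of strain C57BL/6. Per the labels' protocols, total RNA was isolated with a kit for small samples, amplified to cDNA, made into sense-strand target, fragmented and labelled with biotin. Long-term hematopoietic stem cells (LT-HSC) and granulocyte macrophage progenitors (GMP) were sorted from wild-type bone marrow, and lines that had been immortalized from each kind of cell were grown in liquid medium with or without doxycycline (dox). MLL-AF9 is a fusion of the human KMT2A (MLL) and MLLT3 (AF9) genes that causes acute myeloid leukaemia, and in such lines doxycycline is known to switch the fusion on. The hours are given as in the labels, and whether they count from adding or from withdrawing dox is not given in the sources used here.

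The deposited values are log2 probe set signals that the authors had processed, with 34760 probe sets per array. Per the submitters' processing notes, limma and R 3.1.1 were used. The methods of background correction, summarisation and normalization are not given in the sources used here. The scale was read from the values: array medians lay between 5.81 and 5.91, interquartile ranges between 2.68 and 2.92, minimums between 1.75 and 2.15 and maximums between 12.96 and 13.08. No array was identical to another. The number of arrays limits the precision.

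Of the probe sets, 21640 carried 1 gene symbol, 1321 carried several and 11799 had no symbol in the annotation used here. The RefSeq gene table of assembly GRCm38.p6 matched 21553 of the annotated entries and served only for names and for the order of neighbouring genes, since the array's own build was not named. Each of 19937 genes was represented by the probe set with the highest mean over all arrays among those with 1 symbol, and 954 genes had more than 1 such probe set. No filter on dim probe sets was applied, and probe sets with several symbols or none were left out of the gene tests.

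Arrays were grouped by the labels into 8 groups: sorted LT-HSC (n = 4), sorted GMP (n = 4), LT-HSC-derived lines with dox at 48 h (n = 2) and 72 h (n = 3), LT-HSC-derived lines without dox at 48 h (n = 3) and 72 h (n = 3), and GMP-derived lines at 48 h with dox (n = 4) and without (n = 3). A linear model with a mean for every group was fitted to all 26 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), so that all groups shared the spread of a gene. There were 9 comparisons of group pairs and 2 contrasts of dox effects (interactions). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, 2-sided. Differences are given as log2 values with the standard error (SE) of the fit. The labels call the replicates biological. Cultured replicates carry line names, but nothing says that the sorted replicates came from separate animals, so their p-values measure only the spread between these samples.

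Before the data were examined, 25 gene lists with 398 members were fixed from general knowledge, of which 359 were measured: HSC genes, MLL fusion targets, primary granule genes, late neutrophil genes, monocyte and macrophage genes, mast cell and basophil genes, megakaryocyte genes, erythroid genes, B cell genes, T and NK cell genes, stromal and endothelial genes, EMT (epithelial-mesenchymal transition) genes, epithelial genes, migration and invasion genes, proliferation genes, p53 target genes, MYC and nucleolar genes, interferon response genes, NF-kB and inflammatory genes, immediate early genes, ATF4 stress genes, glycolysis and hypoxia genes, cholesterol synthesis genes, MHC class II genes and ribosomal protein genes. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. In addition, the 200 genes with the highest and the 200 with the lowest moderated t in sorted GMP over sorted LT-HSC, among those called with at least a 2-fold difference, were tested as sets in the cultured lines.

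The groups, the comparisons, the tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined. Named genes were, in each comparison, up to 8 of the largest increases and 8 of the largest decreases among called genes whose arrays did not overlap between the groups and whose higher group lay above the median of all probe sets; up to 4 members with the largest difference of the central lists and of any list that passed; and Kmt2a, Mllt3, Mecom, Zeb1, Tcf4, Erg, Hoxa9 and Meis1. Symbols of predicted genes, microRNAs, olfactory and vomeronasal receptors and immunoglobulin or T cell receptor segments were left out. The procedure was tested on simulated data with the residual spread of each gene. In the comparison of LT-HSC-derived lines at 48 h, run on 19937 genes, it called 58.2% of genes changed by 0.5 log2, 97.0% of those changed by 1 and 98.5% of those changed by 2, with 11 false calls. The simulated noise was independent between arrays, with a single spread per gene for all groups. It held no deviation shared by a line and no arrays of unequal quality, so these shares need not hold for the real arrays.

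Dox and no-dox cultures of the same named line were taken as pairs. Arrays of the same line deviated together from their group means in the dox comparisons at 48 h, with correlations across genes of 0.34 and 0.21 in LT-HSC-derived lines and 0.29, 0.33 and 0.40 in GMP-derived lines. At 72 h the values were 0.32, -0.06 and 0.26. No source states a block, so the fits had none, and the line as a block was an alternative. The other alternatives were quantile normalization, median centring, a filter on dim genes, array weights, a prior with trend and robust settings, the mean of a gene's probe sets or each of its other probe sets, only the groups compared, a 2-fold threshold, other set sizes and leaving out each array in turn. Where leaving out an array left a group with 1 array, that array was assumed to vary like the other groups.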

Results

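Expression was measured on 26 arrays in 8 groups: sorted LT-HSC (n = 4), sorted GMP (n = 4), LT-HSC-derived lines with dox at 48 h (n = 2) and 72 h (n = 3) and without dox at 48 h (n = 3) and 72 h (n = 3), and GMP-derived lines at 48 h with dox (n = 4) and without (n = 3). Across probe sets, replicates of a group correlated with r between 0.979 and 0.991. The first principal component held 47.0% of the variance of the genes and the second 14.5%. The residual spread of single arrays ranged from 0.101 to 0.191 log2. Every value below is a log2 difference with its SE unless another unit is given, and the number of arrays limits its precision.

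Sorted GMP were compared with sorted LT-HSC to describe how the normal counterparts of the immortalized lines differ (n = 4 and 4). Genes of myeloid granules were far higher in GMP: Ctsg, which encodes cathepsin G, by 5.69 ± 0.16 (adjusted p = 1.38e-18), the GMP marker Ms4a3 by 5.54 ± 0.17 and Elane, neutrophil elastase, by 4.81 ± 0.15. All 12 measured primary granule genes rose, and all 12 did so adjusted over the list alone (camera, adjusted p = 4.3e-20). Stem cell genes went the other way, and all 22 measured HSC genes fell (22 adjusted over the list alone; adjusted p = 2.62e-27). Among them Mecom, a transcription factor needed for stem cell maintenance, fell by 4.50 ± 0.21 (adjusted p = 1.44e-14), the niche factor Angpt1 fell by 4.53 ± 0.43 and the ETS factor Erg fell by 1.65 ± 0.14. The other probe set of Mecom gave -2.31. Mean Mecom lay below the array medians in sorted GMP (4.55), in GMP-derived lines with and without dox (4.67 and 4.55) and in LT-HSC-derived lines without dox at 48 h and 72 h (5.22 and 4.79). Whether these signals lie above background was not analysed here, so the sizes of its differences from these groups are uncertain. The same holds for Zeb1 in GMP-derived lines with and without dox, where its mean lay below the array medians (4.93 and 5.15).

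Other groups also separated the sorted cells. Of 16 MLL fusion targets, 12 fell and 1 rose (12 and 1 adjusted over the list alone; adjusted p = 1.94e-08), with Meis1, a HOX cofactor, at -3.69 ± 0.16 and Hoxa9 at -1.32 ± 0.08. Kmt2a fell by 0.89 ± 0.07 and Mllt3 fell by 2.54 ± 0.11. Of 22 proliferation genes 20 rose (21 adjusted over the list alone; adjusted p = 7.73e-15), with Rrm2, a ribonucleotide reductase subunit, at 1.52 ± 0.12 and the mitotic kinase Aurka at 1.43 ± 0.11. All 9 measured megakaryocyte genes fell (adjusted p = 2.43e-08), with platelet factor Pf4 at -5.11 ± 0.42 and Vwf at -1.54 ± 0.11. Of 14 interferon response genes 12 fell and 1 rose (12 and 2 adjusted over the list alone; adjusted p = 1.36e-07), including Rtp4 (-2.71 ± 0.18) and Oasl2 (-2.24 ± 0.15).

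Some sorted-cell list calls were lost when the correlation between genes was estimated. Of 15 monocyte and macrophage genes 12 rose (12 adjusted over the list alone; adjusted p = 1.13e-11, and adjusted p = 0.0519 with an estimated correlation), with Ly86 at 5.34 ± 0.38 and the chemokine receptor Ccr2 at 4.63 ± 0.23. Of 11 mast cell and basophil genes 7 rose (7 adjusted over the list alone; adjusted p = 0.00951, and adjusted p = 0.425 with an estimated correlation). Among them was the protease gene Mcpt8 at 3.83 ± 0.46. Of 15 immediate early genes, which respond to cell handling, 9 fell (10 adjusted over the list alone; adjusted p = 0.000926, and adjusted p = 0.34 with an estimated correlation), with Egr1 at -1.78 ± 0.25 and Fosb at -1.41 ± 0.16. Of 12 epithelial genes 4 fell (4 adjusted over the list alone; adjusted p = 0.0331, and adjusted p = 0.195 with an estimated correlation), with the tight junction gene Tjp1 at -2.52 ± 0.27. That list call ended with the dim filter (adjusted p = 0.128) and quantile normalization (adjusted p = 0.0667). Of 10 erythroid genes 4 fell (4 adjusted over the list alone; adjusted p = 0.0403, and adjusted p = 0.441 with an estimated correlation), with the carbonic anhydrase Car2 at -3.88 ± 0.25. Without sorted LT-HSC replicate 2 or sorted GMP replicate 3 the erythroid list did not pass (adjusted p = 0.095 and 0.0634), nor did it with the dim filter (0.0702), quantile normalization (0.0846) or the trended prior (0.0539). The B cell and the T and NK cell lists passed in none of the 11 comparisons, with a lowest camera adjusted p of 0.216 for each.

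The 23 EMT genes split in the sorted cells: 8 were higher in GMP and 5 lower (8 and 5 adjusted over the list alone), with a median of -0.001, a mean of 0.26 and no call for the list (camera, adjusted p = 0.455). Lgals1 (galectin 1) rose by 3.23 ± 0.14 and Fn1 (fibronectin) by 2.16 ± 0.37, while the EMT factor Zeb1 fell by 2.03 ± 0.13 and Tcf4 fell by 0.84 ± 0.10. Zeb1, Tcf4, Mecom and Erg are recalled as genes that the study picked from such samples, so their direction, and that of the EMT and HSC lists in the lines, is not independent evidence. In all, limma called 6402 genes in this comparison, 3359 higher and 3043 lower in GMP, and camera 12 of 25 lists at the preset correlation. Not all of these lists are given here.

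Dox and no-dox cultures of LT-HSC-derived lines at 48 h were compared to show how expression differs with dox in lines of stem cell origin (n = 2 and 3). Among genes with 1 symbol, Hprt, an enzyme of purine salvage, had the largest increase, 3.00 ± 0.20 (adjusted p = 2.49e-09), with dox arrays between 10.6 and 10.8 and no-dox arrays between 7.51 and 7.95. Mecom rose by 2.14 ± 0.27 (adjusted p = 0.000267), with dox arrays at 7.01 and 7.72 and no-dox arrays between 4.78 and 5.80. Its call ended when only the groups compared were fitted (adjusted p = 0.0636), and its other probe set gave 0.98 (adjusted p = 0.106). Of 16 MLL fusion targets 7 rose (12 adjusted over the list alone; camera, adjusted p = 4.38e-22), with Hoxa9 at 0.75 ± 0.10 (adjusted p = 0.000811) and Meis1 at 1.27 ± 0.20 (adjusted p = 0.00286). Meis1 did not pass without dox replicate 2 (adjusted p = 0.113) or with only the groups compared (adjusted p = 0.21). Kmt2a (0.22 ± 0.09, adjusted p = 0.535), Mllt3 (-0.03 ± 0.14, adjusted p = 0.997) and Zeb1 (0.14 ± 0.17, adjusted p = 0.974) were not called.

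In the same comparison at 48 h, of 7 MHC class II genes 2 fell with dox (4 adjusted over the list alone; camera, adjusted p = 3.09e-09), and H2-Aa fell by 1.35 ± 0.25 (adjusted p = 0.00926). Of 14 NF-kB and inflammatory genes 1 fell (6 adjusted over the list alone; adjusted p = 3e-07). Of 14 glycolysis and hypoxia genes 12 fell adjusted over the list alone but none over all genes (adjusted p = 2e-15). Of 15 monocyte and macrophage genes 1 fell (4 adjusted over the list alone; adjusted p = 4.07e-10, and adjusted p = 0.0762 with an estimated correlation). It was the mannose receptor gene Mrc1, which fell by 3.38 ± 0.54. Of 18 late neutrophil genes 1 fell (5 adjusted over the list alone; adjusted p = 2.02e-06, and adjusted p = 0.172 with an estimated correlation). Of 19 ATF4 stress genes none passed over all genes (1 rose adjusted over the list alone), with a list median of 0.13 (adjusted p = 0.000133, and adjusted p = 0.0646 with an estimated correlation). Of 13 cholesterol synthesis genes none passed over all genes, with a list median of -0.17 (adjusted p = 0.000861, and adjusted p = 0.183 with an estimated correlation). The calls of H2-Aa and Mrc1 ended without dox replicate 1 (adjusted p = 0.169 and 0.0601) and without dox replicate 2 (adjusted p = 0.116 and 0.103), and that of H2-Aa with only the groups compared (adjusted p = 0.265).

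At 48 h the 23 EMT genes did not move as a list in LT-HSC-derived lines (1 fell; 1 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.109). The list passed downward with the line as a replicate block (adjusted p = 0.0214), without dox replicate 2 (0.0263) and without no-dox replicate 3 (0.0398). The 22 HSC genes, 2 of which rose, gave an adjusted p of 0.109. It became 0.0044 with the line as a block, 0.0417 without dox replicate 1 and 0.00677 without no-dox replicate 3. Camera called 14 of 25 lists at the preset correlation, 4 higher and 10 lower with dox, not all of which are given here, and 5 with an estimated correlation. In this comparison limma called 88 genes, 31 higher and 57 lower with dox, and 1456 had an unadjusted p under 0.05. The count was 295 with the line as a replicate block, 12 and 10 without dox replicates 1 and 2. Without no-dox replicates 2 and 3 it was 37 and 48.

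At 72 h the same lines were compared again (n = 3 and 3). Hprt rose by 3.53 ± 0.18 (adjusted p = 6.1e-12), Mecom by 2.64 ± 0.24 (adjusted p = 3.73e-07), Cth, an enzyme that makes cysteine, by 2.22 ± 0.31 and the glutathione transferase gene Gsta4 by 1.87 ± 0.17. The other probe set of Mecom gave 1.48. Of 16 MLL fusion targets 11 rose (14 adjusted over the list alone; camera, adjusted p = 6.43e-18), with Meis1 at 1.61 ± 0.18, Eya1 at 1.65 ± 0.29, Hoxa5 at 1.25 ± 0.19 and Hoxa9 at 0.85 ± 0.09. All 7 MHC class II genes fell (7 adjusted over the list alone; adjusted p = 2.73e-13), among them Cd74 (invariant chain) by -2.42 ± 0.30, H2-Aa by -2.40 ± 0.22 and H2-Ab1 by -2.39 ± 0.24. Of 19 ATF4 stress genes 7 rose (8 adjusted over the list alone; adjusted p = 3.91e-08), with asparagine synthetase, Asns, at 0.75 ± 0.11. These were 7 of its 10 biosynthesis and transport members (median 0.46), and 0 of its 7 stress regulators and effectors were called (median 0.15). Of 17 migration and invasion genes 7 fell and 1 rose (11 and 2 adjusted over the list alone; adjusted p = 0.000145), with the urokinase receptor Plaur at -1.51 ± 0.24 and the protease Adam8 at -1.09 ± 0.18. Of 14 NF-kB and inflammatory genes 3 fell (9 adjusted over the list alone; adjusted p = 0.000111).

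Further lists moved with dox at 72 h but not with an estimated correlation. Of 15 monocyte and macrophage genes 9 fell (14 adjusted over the list alone; camera, adjusted p = 5.88e-11, and adjusted p = 0.0623 with an estimated correlation), including Mrc1 (-3.69 ± 0.49) and the receptor Csf1r (-1.36 ± 0.30). Of 18 late neutrophil genes 7 fell (9 adjusted over the list alone; adjusted p = 1.37e-07, and adjusted p = 0.103 with an estimated correlation), with lactoferrin, Ltf, at -3.11 ± 0.55. Of 15 immediate early genes 8 fell (10 adjusted over the list alone; adjusted p = 8.17e-09, and adjusted p = 0.0623 with an estimated correlation), with Egr2 at -2.70 ± 0.43 and Jun at -1.44 ± 0.29. Of 14 glycolysis and hypoxia genes 7 fell (12 adjusted over the list alone; adjusted p = 2.24e-07, and adjusted p = 0.139 with an estimated correlation), with the glucose transporter Slc2a1 at -0.83 ± 0.18. The 16 MYC and nucleolar genes, 2 of which rose (7 adjusted over the list alone), gave an adjusted p of 1.42e-07 (adjusted p = 0.0716 with an estimated correlation). The 13 ribosomal protein genes had a median of 0.10 with no single call over all genes (adjusted p = 0.000272, and adjusted p = 0.0716 with an estimated correlation).

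Among the genes linked to stem cells and EMT, Mecom, Erg (0.86 ± 0.16) and Gimap6 (1.41 ± 0.13) rose at 72 h and were the 3 called HSC genes of 22 (3 adjusted over the list alone; camera, adjusted p = 0.00577, and adjusted p = 0.231 with an estimated correlation). That list call ended without no-dox replicate 2 (adjusted p = 0.0696) and with the dim filter (0.0579). Of 23 EMT genes 2 rose and 5 fell (2 and 6 adjusted over the list alone), and the list was lower with dox (adjusted p = 0.0252, and adjusted p = 0.139 with an estimated correlation). The EMT list did not pass without no-dox replicate 2 (adjusted p = 0.112) or with array weights (adjusted p = 0.0555). Zeb1 rose by 0.61 ± 0.15 (adjusted p = 0.015) and Tcf4 by 0.46 ± 0.12 (adjusted p = 0.0201), while the matrix genes Fn1 (-2.89 ± 0.43) and Tgfbi (-2.65 ± 0.27) fell. Kmt2a was at 0.27 ± 0.08 (adjusted p = 0.0493). Its call ended without dox replicates 1, 2 and 3 (0.0595, 0.0866 and 0.214) and no-dox replicates 1 and 3 (0.12 and 0.152), with quantile normalization (0.143), with median centring (0.0519) and with only the groups compared (0.175). The Zeb1 call ended without dox replicate 3 (adjusted p = 0.0997), and the Tcf4 call ended without dox replicate 2 (0.131), without no-dox replicate 3 (0.105) and with only the groups compared (0.128). At 72 h camera called 14 of 25 lists at the preset correlation, 6 higher and 8 lower, not all of which are given here. Over all genes limma called 1425, 683 higher and 742 lower with dox, against 859, 903 and 901 without dox replicate 1, no-dox replicate 1 and dox replicate 3.

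In GMP-derived lines at 48 h the same question was asked in cells of committed progenitor origin (n = 4 and 3). The largest decreases with dox were in neutrophil granule genes: Ltf fell by 4.81 ± 0.51 (adjusted p = 1.21e-06), the lipocalin gene Lcn2 fell by 3.73 ± 0.33, the cathelicidin gene Camp fell by 3.46 ± 0.50 and Chil3 fell by 3.45 ± 0.33. Of 18 late neutrophil genes 15 fell (17 adjusted over the list alone; camera, adjusted p = 7.59e-27). Hprt rose by 3.11 ± 0.16 (adjusted p = 2.36e-11), the ephrin receptor gene Epha7 by 2.74 ± 0.28, Cth by 2.28 ± 0.29 and the progenitor marker Cd34 by 2.07 ± 0.25. Of 16 MLL fusion targets 13 rose (14 adjusted over the list alone; adjusted p = 4.07e-23), with Meis1 at 2.46 ± 0.17, Mef2c at 1.60 ± 0.12, the survival gene Bcl2 at 1.55 ± 0.10 and Hoxa9 at 0.99 ± 0.09. Mecom (0.12 ± 0.22, adjusted p = 0.871) and Zeb1 (-0.22 ± 0.14, adjusted p = 0.451) were not called.

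The MYC and nucleolar list and the ATF4 stress list rose in GMP-derived lines with dox. Of 16 MYC and nucleolar genes 15 rose (16 adjusted over the list alone; camera, adjusted p = 6.92e-17), with the nucleolar proteins Nop56 at 0.73 ± 0.11 and Gnl3 at 0.66 ± 0.10. Of 19 ATF4 stress genes 11 rose (14 adjusted over the list alone; adjusted p = 4.45e-12), with the cystine transporter Slc7a11 at 1.31 ± 0.15 and the serine enzyme Shmt2 at 0.81 ± 0.13. Of the list's 10 biosynthesis and transport members 9 rose (median 0.58), against 2 of its 7 stress regulators and effectors (median 0.22). Of 15 immediate early genes 6 fell (11 adjusted over the list alone; adjusted p = 4.99e-10), with Egr2 at -1.90 ± 0.40 and Klf6 at -1.59 ± 0.13. Of 17 migration and invasion genes 6 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.000136), with Plaur at -1.53 ± 0.22 and the integrin gene Itgb2 at -0.73 ± 0.14. Of 14 NF-kB and inflammatory genes 2 fell (2 adjusted over the list alone; adjusted p = 0.000407), including Nfkbia (-0.86 ± 0.14). Of 15 monocyte and macrophage genes 9 fell (11 adjusted over the list alone; adjusted p = 1.06e-08, and adjusted p = 0.108 with an estimated correlation), with Mrc1 at -2.37 ± 0.45 and lysozyme, Lyz2, at -1.78 ± 0.34. Of 14 glycolysis and hypoxia genes 4 fell (8 adjusted over the list alone; adjusted p = 2.54e-05, and adjusted p = 0.25 with an estimated correlation).

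Of 23 EMT genes in GMP-derived lines, 1 rose and 4 fell with dox (1 and 6 adjusted over the list alone; camera, adjusted p = 0.0186, and adjusted p = 0.145 with an estimated correlation), and the list did not pass without no-dox replicate 2 (adjusted p = 0.068). Tcf4 rose by 1.13 ± 0.11 (adjusted p = 4.63e-07), while Fn1 (-2.88 ± 0.40) and Tgfbi (-2.23 ± 0.25) fell. Erg was at 0.22 ± 0.15 (adjusted p = 0.506), but was called with the line as a replicate block (0.36, adjusted p = 0.0332). Here limma called 2179 genes, 1146 higher and 1033 lower with dox, and 1224 without no-dox replicate 2. Of the 25 lists camera called 13 at the preset correlation, 4 higher and 9 lower, not all of which are given here.

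**Figure D1:**
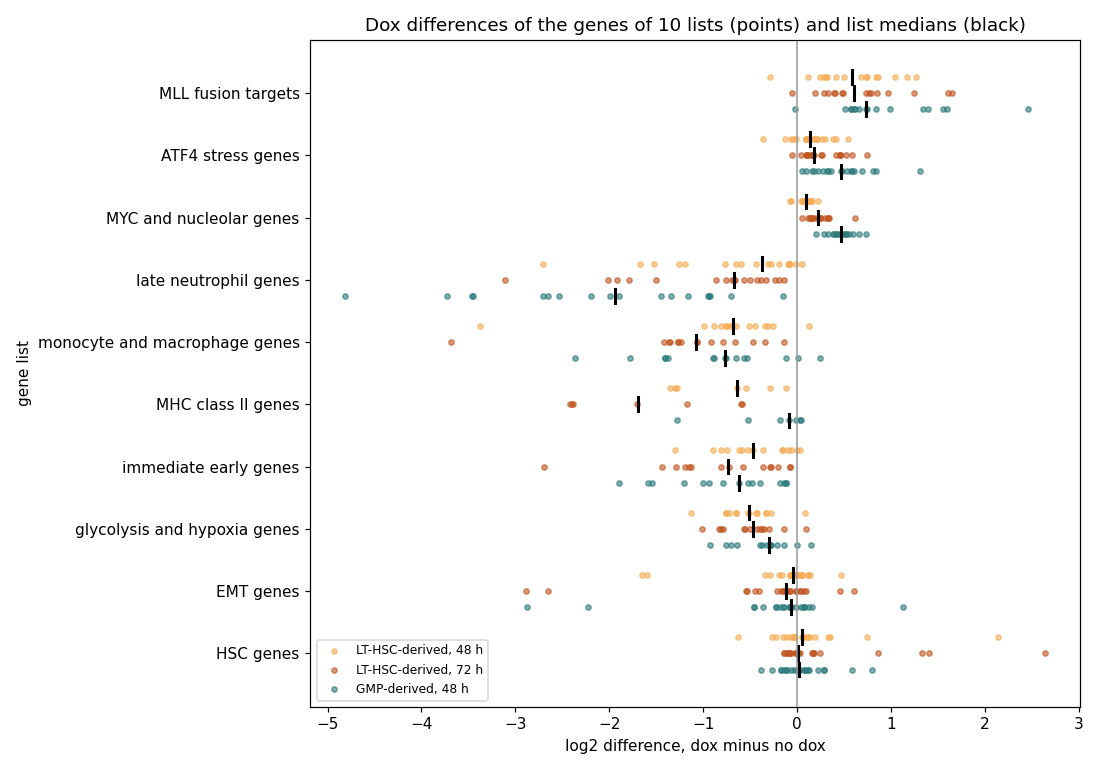
Log2 difference between dox and no-dox arrays (horizontal axis) of the measured genes of 10 lists in the 3 dox comparisons, 1 point per gene, with each list's median as a black bar. The medians of the MLL fusion targets lie at 0.59, 0.61 and 0.74, and those of the late neutrophil genes at -0.38, -0.67 and -1.94, for LT-HSC-derived lines at 48 h and 72 h and GMP-derived lines at 48 h.

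The dox responses of lines of either origin, which share no array, were then set side by side. Of the 31 genes higher with dox in LT-HSC-derived lines at 48 h, 24 were also called higher in GMP-derived lines (1.78 for independent lists), and of the 57 lower genes 46 were also called lower (2.95 for independent lists). The calls were not independent, since both used the same spread per gene from all 26 arrays. Genes of low spread can thus be called in both. The counts for independent lists were taken over all 19937 genes, dim ones included. With only the groups compared fewer higher genes were shared (below). Across all genes, which are not independent replicates, the effects correlated with a Pearson r of 0.572 and a Spearman rho of 0.318. At 72 h 372 higher and 394 lower genes were shared with GMP-derived lines (39.3 and 38.5 for independent lists), with a Pearson r of 0.669 and a Spearman rho of 0.443. The shared counts at 48 h were 6 and 4 without LT-HSC-derived dox replicate 1, 4 and 4 without dox replicate 2, 12 and 17 without no-dox replicate 2 and 14 and 25 without no-dox replicate 3. With the line as a replicate block they were 42 and 200.

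The difference of the dox effects at 48 h was tested as an interaction, LT-HSC-derived minus GMP-derived. The lectin receptor gene Clec4b2 stood 3.11 ± 0.40 higher in it (adjusted p = 0.000691) and Bcl2 stood at -1.43 ± 0.16 (adjusted p = 8.76e-05), since Bcl2 rose with dox in GMP-derived lines. Mecom differed by 2.03 ± 0.35 (adjusted p = 0.0109), but not without LT-HSC-derived dox replicate 2 (adjusted p = 0.158), with only the groups compared (0.0912) or in its other probe set (0.95, adjusted p = 0.417). Meis1, which was at -1.19 ± 0.26 (adjusted p = 0.0575), was called with the line as a block (-1.06, adjusted p = 0.0114), with the line as a random effect (0.0401), with array weights (0.0415), with the dim filter (0.0461), and without LT-HSC-derived no-dox replicates 1 and 2 (0.0221 and 0.0418). Late neutrophil genes fell less in LT-HSC-derived lines, where 3 of 18 differed (12 adjusted over the list alone; camera, adjusted p = 2.23e-20). MLL fusion targets (3 of 16 lower adjusted over the list alone; adjusted p = 3.6e-06), MYC and nucleolar genes (10 of 16; adjusted p = 3.86e-13) and ATF4 stress genes (3 of 19; adjusted p = 4.03e-06) rose less there. Without dox, LT-HSC-derived lines were already lower in late neutrophil genes and higher in MLL fusion targets and MYC and nucleolar genes at the preset correlation (below). The smaller changes thus go with unequal levels without dox, and whether these account for them was not tested. In the interaction limma called 46 genes, 32 higher and 14 lower, and 1742 had an unadjusted p under 0.05. The count was 98 with the line as a replicate block, 18 and 8 without LT-HSC-derived dox replicates 1 and 2, 28 without no-dox replicate 3, 28 without GMP-derived dox replicate 1 and 29 without GMP-derived no-dox replicate 2.

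Lines of both origins were compared under dox at 48 h to show how lines of either origin differ (n = 2 and 4). LT-HSC-derived lines were higher in Scin, an actin-severing protein, by 3.97 ± 0.26 (adjusted p = 1.72e-09), in the receptor genes Il18r1 by 3.43 ± 0.34 and Flt3 by 2.80 ± 0.31, in Mecom by 2.69 ± 0.25 and in Zeb1 by 2.37 ± 0.16 (adjusted p = 1.91e-09). The sizes for Mecom and Zeb1 are uncertain, since their means in GMP-derived lines lay below the array medians. The other probe set of Mecom gave 1.59. GMP-derived lines were higher in the tetraspanin gene Tspan12, which stood at -2.59 ± 0.31, and in the amino acid transporter gene Slc36a4 at -1.97 ± 0.21. Of 22 HSC genes 4 were higher in LT-HSC-derived lines (5 adjusted over the list alone; camera, adjusted p = 0.000152, and adjusted p = 0.232 with an estimated correlation), with a list median of 0.09. Lists of other cell types moved as well. Of 11 mast cell and basophil genes 1 was higher (5 adjusted over the list alone; adjusted p = 0.00105, and adjusted p = 0.311 with an estimated correlation). Of 9 megakaryocyte genes 1 was higher (2 adjusted over the list alone; adjusted p = 0.000152, and adjusted p = 0.232 with an estimated correlation). Of 10 erythroid genes 2 were higher (3 adjusted over the list alone; adjusted p = 0.0159, and adjusted p = 0.345 with an estimated correlation). Of 12 primary granule genes 1 was lower (3 adjusted over the list alone; adjusted p = 0.0119, and adjusted p = 0.24 with an estimated correlation). The erythroid and primary granule calls ended without LT-HSC-derived dox replicate 2 (adjusted p = 0.149 and 0.116), and the erythroid one with the dim filter (0.068). Of 18 late neutrophil genes 1 was higher (4 adjusted over the list alone; adjusted p = 1.9e-06, and adjusted p = 0.232 with an estimated correlation), namely Chil3 at 2.38 ± 0.37. Of 7 MHC class II genes 2 were higher (2 adjusted over the list alone; adjusted p = 0.000208, and adjusted p = 0.232 with an estimated correlation), with H2-Aa at 2.03 ± 0.23. Of 23 EMT genes Zeb1 was the only call over all genes, and the list had a median of -0.000 and a mean of 0.08 (adjusted p = 0.48). Tcf4, Erg, Hoxa9 and Meis1 were not called (0.09, 0.27, -0.06 and 0.23). The lists that camera called at the preset correlation were 10 of 25, not all of which are given here, and 0 with an estimated correlation. In all, 421 genes were called with limma, 233 higher and 188 lower in LT-HSC-derived lines, against 237 and 110 without LT-HSC-derived dox replicates 1 and 2.

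Without dox at 48 h the lines of both origins differed in more genes (n = 3 and 3). Scin (4.14 ± 0.25, adjusted p = 1.3e-10), H2-Aa (3.30 ± 0.22), Flt3 (2.46 ± 0.29), Bcl2 (2.23 ± 0.11), Zeb1 (2.01 ± 0.15, adjusted p = 5.77e-09) and Meis1 (1.42 ± 0.18) were higher in LT-HSC-derived lines. The size for Zeb1 is again uncertain, since its mean in GMP-derived lines lay below the array medians. Tceal8 (-3.46 ± 0.55), the RNA-binding protein gene Elavl2 (-3.03 ± 0.46), Slc36a4 (-2.36 ± 0.20) and the neutrophil antigen gene Cd177 (-1.64 ± 0.24) were lower. Of 16 MYC and nucleolar genes 10 were higher (12 adjusted over the list alone; camera, adjusted p = 8.04e-11, and adjusted p = 0.0777 with an estimated correlation). Of 7 MHC class II genes 4 were higher (5 adjusted over the list alone; adjusted p = 2.75e-07, and adjusted p = 0.0504 with an estimated correlation). Of 18 late neutrophil genes 5 were lower (9 adjusted over the list alone; adjusted p = 1.19e-07, and adjusted p = 0.155 with an estimated correlation). Of 12 primary granule genes 5 were lower (5 adjusted over the list alone; adjusted p = 0.00331, and adjusted p = 0.155 with an estimated correlation). Cebpe stood at -0.85 ± 0.13 and Elane at -0.82 ± 0.17. Of 16 MLL fusion targets 5 were higher (5 adjusted over the list alone; adjusted p = 7.21e-05, and adjusted p = 0.116 with an estimated correlation). Of 11 mast cell and basophil genes 6 were higher (6 higher and 1 lower adjusted over the list alone; adjusted p = 8.07e-05, and adjusted p = 0.209 with an estimated correlation). Of 22 HSC genes 5 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.0231, and adjusted p = 0.413 with an estimated correlation). The HSC call ended without LT-HSC-derived no-dox replicate 3 (0.16), without GMP-derived no-dox replicate 2 (0.0502), with array weights (0.053) and with only the groups compared (0.0671). In all, camera called 11 of 25 lists at the preset correlation, 9 higher and 2 lower, not all of which are given here. It called 0 with an estimated correlation.

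Of the genes linked to EMT, Tcf4 was higher by 0.75 ± 0.12 (adjusted p = 0.000292) in LT-HSC-derived lines without dox, and 2 of 23 EMT genes were higher and 1 lower (2 and 1 adjusted over the list alone; camera, adjusted p = 0.586). Mecom was at 0.67 ± 0.24 (adjusted p = 0.105) and was called without LT-HSC-derived no-dox replicate 2 (0.89, adjusted p = 0.0414) and with the mean of its probe sets (0.65, adjusted p = 0.0493). In all, limma called 1355 genes, 702 higher and 653 lower, against 743 without LT-HSC-derived no-dox replicate 3 and 880 without GMP-derived no-dox replicate 2.

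**Figure D2:**
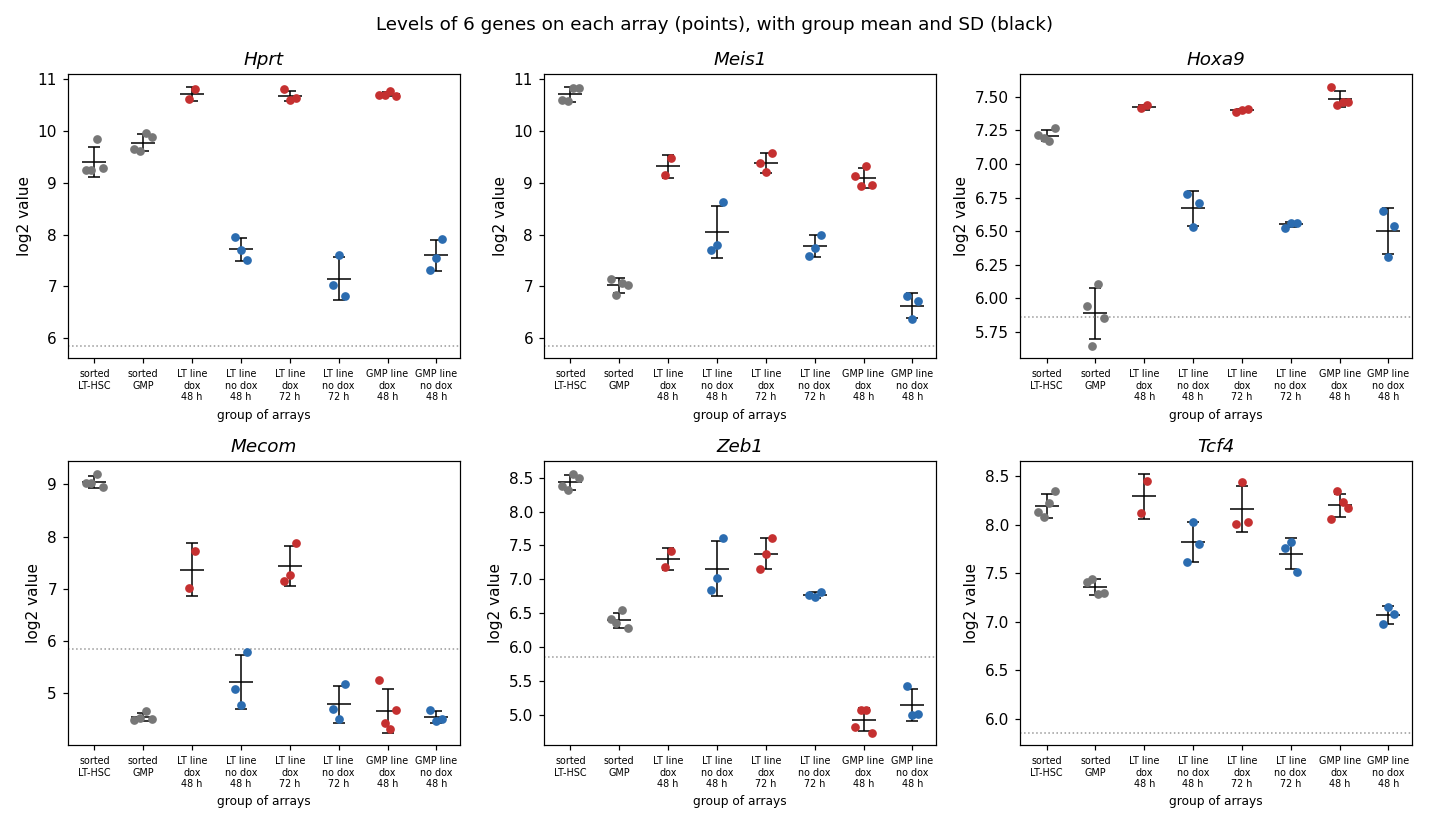
Log2 level (vertical axis) of Hprt, Meis1, Hoxa9, Mecom, Zeb1 and Tcf4 on each array (points) in the 8 groups, with group mean and SD in black; the dotted line is the mean of the array medians. Mean Hprt is 10.7 in each dox group against 7.72, 7.15 and 7.60 without dox, and mean Mecom is 7.37 and 7.44 in LT-HSC-derived lines with dox against 4.67 in GMP-derived lines with dox.

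The genes that set sorted LT-HSC and GMP apart were followed in the lines. The 200 genes higher in sorted LT-HSC were higher in LT-HSC-derived than in GMP-derived lines under dox, with a median of 0.11 and 68.0% of genes above 0 (28 called higher and 2 lower; camera, adjusted p = 2.12e-12, and adjusted p = 0.028 with an estimated correlation). The 200 genes higher in sorted GMP were lower there, with a median of -0.12 (4 called higher and 15 lower; adjusted p = 8.92e-07, and adjusted p = 0.0868 with an estimated correlation). Without dox the medians were 0.08 (adjusted p = 7.96e-06, and adjusted p = 0.105 with an estimated correlation) and -0.20 (adjusted p = 9.83e-10, and adjusted p = 0.0681 with an estimated correlation). With dox, the genes of sorted GMP were lower in GMP-derived lines, with a median of -0.11 (adjusted p = 1.85e-07, and adjusted p = 0.129 with an estimated correlation), and in LT-HSC-derived lines at 48 h, with a median of -0.075 (adjusted p = 6.68e-06, and adjusted p = 0.208 with an estimated correlation). The genes of sorted LT-HSC had a median of -0.01 and a mean of 0.02 there and did not pass (adjusted p = 0.501), although without no-dox replicate 3 they did (0.0101).

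With dox at 72 h, the genes of sorted LT-HSC were higher (median 0.02; camera, adjusted p = 0.0074, and adjusted p = 0.386 with an estimated correlation) and those of sorted GMP lower (median -0.075; adjusted p = 0.0159, and adjusted p = 0.386 with an estimated correlation). The first of these calls ended without no-dox replicate 2 (0.0672), without dox replicate 3 (0.0781), with the dim filter (0.159) and with 50 genes in the set (0.11). The second ended without no-dox replicates 1 and 2 (0.155 and 0.391) and dox replicates 2 and 3 (0.197 and 0.0781) and with median centring (0.0858). With 50 genes in that set its median was 0.033.

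LT-HSC-derived lines with dox at 72 h were compared with sorted LT-HSC to show how far the lines had moved from their normal counterpart (n = 3 and 4). Stem cell genes were much lower: 20 of 22 HSC genes fell (21 adjusted over the list alone; camera, adjusted p = 3.5e-20), with the transcription factor gene Hlf at -3.88 ± 0.10 (adjusted p = 6.31e-19), the angiopoietin receptor gene Tek at -3.52 ± 0.13 and Mecom at -1.61 ± 0.22. The other probe set of Mecom gave -0.76. All 12 primary granule genes rose (12 adjusted over the list alone; adjusted p = 8.65e-18), with Ms4a3 at 5.78 ± 0.18, Ctsg at 5.52 ± 0.17 and Elane at 3.89 ± 0.16. Of 13 cholesterol synthesis genes 12 rose (12 adjusted over the list alone; adjusted p = 8.41e-13), with Fdps at 2.36 ± 0.09 and Hmgcs1 at 2.05 ± 0.16. Of 19 ATF4 stress genes 16 rose (16 adjusted over the list alone; adjusted p = 4.74e-10), with Slc7a11 at 2.93 ± 0.15 and Asns at 2.46 ± 0.10. Of 15 immediate early genes 14 fell (14 adjusted over the list alone; adjusted p = 2.61e-12), with Fosb at -4.53 ± 0.17 and Jun at -3.74 ± 0.27. Of 14 interferon response genes 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 9e-08), with Rtp4 at -3.18 ± 0.19.

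Myeloid markers were also higher in these lines than in sorted LT-HSC. Of 15 monocyte and macrophage genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; camera, adjusted p = 1.69e-07, and adjusted p = 0.135 with an estimated correlation), with Ccr2 at 5.07 ± 0.25. Of 18 late neutrophil genes 11 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 8.84e-07, and adjusted p = 0.135 with an estimated correlation), with Chil3 at 4.37 ± 0.33. Of 22 proliferation genes 14 rose (16 adjusted over the list alone; adjusted p = 6.37e-08, and adjusted p = 0.111 with an estimated correlation). Among MLL fusion targets 2 of 16 rose and 5 fell (2 and 7 adjusted over the list alone; adjusted p = 0.26), with the receptor gene Flt3 at 1.52 ± 0.27, Meis1 at -1.32 ± 0.17 and Zfp521 at -2.49 ± 0.11. Of 23 EMT genes 3 rose and 6 fell (3 and 6 adjusted over the list alone; adjusted p = 0.643), with Lgals1 at 3.26 ± 0.15 and Zeb1 at -1.06 ± 0.14. Erg fell by 1.20 ± 0.15. Culture and the fusion differed together in this contrast and cannot be told apart. In it limma called 6768 genes, 3379 higher and 3389 lower in the lines, and camera 13 of 25 lists at the preset correlation. Not all of these lists are given here.

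GMP-derived lines with dox at 48 h were compared with sorted GMP in the same way (n = 4 and 4). The prostaglandin-degrading enzyme gene Hpgd was higher by 6.17 ± 0.73 and Myl10 by 4.26 ± 0.20. All 13 cholesterol synthesis genes rose (13 adjusted over the list alone; camera, adjusted p = 1.34e-25), with Cyp51 at 1.94 ± 0.08. Of 19 ATF4 stress genes 14 rose (16 adjusted over the list alone; adjusted p = 1.37e-20), with Slc7a11 at 3.04 ± 0.14. Of 16 MLL fusion targets 11 rose and 3 fell (11 and 3 adjusted over the list alone; adjusted p = 6.85e-08), with Hoxa5 at 2.24 ± 0.17, Meis1 at 2.07 ± 0.16 and Hoxa9 at 1.59 ± 0.08. Of 15 immediate early genes 12 fell (12 adjusted over the list alone; adjusted p = 5.99e-16), with Jun at -3.29 ± 0.25 and Dusp1 at -3.06 ± 0.19. Of 23 EMT genes 2 rose and 8 fell (2 and 10 adjusted over the list alone; adjusted p = 0.00819, and adjusted p = 0.106 with an estimated correlation), with Tcf4 at 0.85 ± 0.10, Zeb1 at -1.47 ± 0.13 and Fn1 at -2.48 ± 0.37.

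Further list differences between GMP-derived lines and sorted GMP did not hold with an estimated correlation. Of 15 monocyte and macrophage genes 8 fell (8 adjusted over the list alone; camera, adjusted p = 0.00355, and adjusted p = 0.433 with an estimated correlation). Of 11 mast cell and basophil genes 6 fell (6 adjusted over the list alone; adjusted p = 0.00781, and adjusted p = 0.416 with an estimated correlation). Of 22 proliferation genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.0228, and adjusted p = 0.484 with an estimated correlation). Of 14 interferon response genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0258, and adjusted p = 0.416 with an estimated correlation). These 2 list calls ended with the dim filter (0.0532 and 0.164). Of 10 erythroid genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.0453, and adjusted p = 0.433 with an estimated correlation). The erythroid call ended without sorted GMP replicates 1 and 2 (0.0641 and 0.0629) and dox replicate 4 (0.0934). It also ended with the dim filter (0.164), quantile normalization (0.0728), the trended prior (0.0603) and array weights (0.0529). Of 14 glycolysis and hypoxia genes 9 rose (10 adjusted over the list alone; adjusted p = 5.79e-06, and adjusted p = 0.294 with an estimated correlation), with the mitophagy gene Bnip3 at 2.34 ± 0.26. Of 14 NF-kB and inflammatory genes 7 fell (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.000938, and adjusted p = 0.0761 with an estimated correlation), with Tnfaip3 at -1.41 ± 0.12. Of 13 p53 target genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.0282, and adjusted p = 0.102 with an estimated correlation), with the cyclin gene Ccng1 at 0.85 ± 0.08 and the death receptor gene Fas at 0.99 ± 0.20. That list call ended without dox replicate 4 (0.0599) and with the dim filter (0.0539). Of 12 stromal and endothelial genes 3 fell (4 adjusted over the list alone; adjusted p = 0.0228, and adjusted p = 0.386 with an estimated correlation), with Sparc at -1.73 ± 0.39. That list call ended with the dim filter (0.208). In all, limma called 3943 genes, 1998 higher and 1945 lower in the lines, and culture again differed between the groups.

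The LT-HSC-derived lines without dox were compared at 72 h and 48 h to show what differed between these times without dox (n = 3 and 3). MHC class II genes were higher at 72 h: 4 of 7 rose (7 adjusted over the list alone; camera, adjusted p = 1.13e-11), with H2-Ab1 at 1.41 ± 0.24 (adjusted p = 0.0165) and H2-Aa at 1.34 ± 0.22 (adjusted p = 0.0153). Without replicate 1 at 48 h their adjusted p was 0.107 and 0.0621, without replicate 2 at 48 h it was 0.0552 for each, and with only the groups compared it was 0.325 and 0.321. Of 17 migration and invasion genes 1 rose (7 adjusted over the list alone; adjusted p = 0.00065). Of 16 MYC and nucleolar genes 5 fell adjusted over the list alone (adjusted p = 1.42e-08, and adjusted p = 0.0934 with an estimated correlation). At the preset correlation camera called 11 of 25 lists, 6 higher and 5 lower at 72 h, not all of which are given here. With an estimated correlation it called 2. Over all genes limma called 36, 24 higher and 12 lower at 72 h, and 2588 had an unadjusted p under 0.05. The count was 230 with the line as a replicate block. It was 0, 0 and 22 without replicates 1, 2 and 3 at 48 h, with an unadjusted p under 0.05 for 2131 and 2383 genes in the first fits, and 10, 57 and 55 without replicates 1, 2 and 3 at 72 h.

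Whether the dox effect in LT-HSC-derived lines differed between 72 h and 48 h was tested directly. For single genes limma called 0, and 1132 had an unadjusted p under 0.05. With the line as a replicate block 2 genes were called, and 1 and 2 genes without no-dox replicates 1 and 3 at 72 h. The dox difference of MHC class II genes was more negative at 72 h than at 48 h, with a list median of -1.05. Of these genes 4 of 7 differed adjusted over the list alone (camera, adjusted p = 4.38e-06, and adjusted p = 0.078 with an estimated correlation). Without dox they were higher at 72 h than at 48 h (H2-Aa by 1.34). The contrast therefore does not show a further fall in the dox cultures.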

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

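The test of doxycycline itself, that of genes with a signal similar to Hprt and the comparison of unnamed probe sets with Hprt were chosen after the result was seen, and the other tests in this part were chosen before.

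In groups of 4 arrays, the gap between the most extreme array and its neighbour was divided by the range of the group for each of the named genes considered for the text, some of which are given only here. Of 172 pairs of a gene and a group, 15 had an array far from the others, where chance gives about 1 in 20 groups, or 9. In GMP-derived lines with dox these were Car1 (replicate 2, lowest, 0.841), Cpa3 (replicate 1, highest, 0.916), Gnl3 (replicate 2, 0.837), H2-Aa (replicate 4, lowest, 0.955), Hoxa9 (replicate 1, highest, 0.847), Itgb2 (replicate 1, lowest, 0.830), Ngp (replicate 3, highest, 0.891) and Tspan12 (replicate 4, highest, 0.920). In sorted GMP it was Fosb (replicate 4, lowest, 0.879). In sorted LT-HSC these were Ctsg (replicate 1, highest, 0.929), Hlf (replicate 4, lowest, 0.888), Jun (replicate 1, highest, 0.887), Kmt2a (replicate 2, lowest, 0.947), Tek (replicate 1, lowest, 0.859) and Zfp521 (replicate 3, highest, 0.831). Of the 15, 3 each were on sorted LT-HSC replicate 1 and GMP-derived dox replicate 1, and 2 each on GMP-derived dox replicates 2 and 4. The source of these gaps was not tested.

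The dox effects at 48 h differed between origins in a test of the difference itself, in which 46 genes passed. Clec4b2 (3.11) and Bcl2 (-1.43) passed in every fit that left out an array. Chil3 (2.79) did not pass without LT-HSC-derived dox replicate 2 (adjusted p = 0.169) and Mecom (2.03) did not either (0.158). C5ar1 (2.03) did not pass without LT-HSC-derived dox replicate 1 (0.0632), dox replicate 2 (0.169) or no-dox replicate 3 (0.0721), or without GMP-derived no-dox replicate 2 (0.0511). Epha7 (-2.15) did not pass in 9 of the fits that left out an array: without LT-HSC-derived dox replicates 1 and 2 (0.231 and 0.0609) and no-dox replicates 1 and 3 (0.0716 and 0.118), and without GMP-derived dox replicates 1 and 2 (0.0603 and 0.0659) and no-dox replicates 1, 2 and 3 (0.0651, 0.0511 and 0.072). The count of 46 was 18 and 8 without LT-HSC-derived dox replicates 1 and 2, 28 without no-dox replicate 3, and 28 and 29 without GMP-derived dox replicate 1 and no-dox replicate 2.

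The lists that differed between origins were late neutrophil genes (adjusted p = 2.23e-20), MYC and nucleolar genes (3.86e-13), MLL fusion targets (3.6e-06) and ATF4 stress genes (4.03e-06), which also passed with an estimated correlation. MHC class II genes (0.00262, and adjusted p = 0.181 with an estimated correlation) and immediate early genes (0.00755, and adjusted p = 0.61 with an estimated correlation) did so only at the preset correlation. The immediate early list did not pass without LT-HSC-derived no-dox replicate 1 (0.229), LT-HSC-derived dox replicate 2 (0.41) or GMP-derived no-dox replicate 2 (0.472). Between 72 h and 48 h the dox effect in LT-HSC-derived lines differed for MHC class II genes (4.38e-06, and adjusted p = 0.078 with an estimated correlation), MYC and nucleolar genes (0.00151), ATF4 stress genes (0.0116) and immediate early genes (0.0337), with adjusted p = 0.614 for the last 3 with an estimated correlation. The ATF4 list did not pass there without LT-HSC-derived dox replicate 2 at 48 h (0.0823) or with the dim filter (0.0664). The immediate early list did not pass without no-dox replicate 1 (0.288) and dox replicate 2 (0.698) at 48 h, or without no-dox replicate 2 (0.359) and dox replicate 3 (0.114) at 72 h.

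Probe sets without a gene name, which the report's comparisons do not use, also responded to dox. Of 11799, limma called 37 higher with dox in LT-HSC-derived lines at 48 h, 257 at 72 h and 300 in GMP-derived lines, with largest increases of 3.52, 3.96 and 5.40, and 1, 105 and 170 lower. Of the higher ones 31, 65 and 65 correlated above 0.8 with Hprt over the 26 arrays. Among 21 other genes higher in each of the 3 dox comparisons the highest such counts were 19, 27 and 28 (for Thada) and the medians 1, 4 and 4.

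Among genes with 1 symbol, Hprt had the largest dox increase in each of the 3 dox comparisons (3.00, 3.53 and 3.11). A general rise of purine genes as the whole cause is argued against: of 12 others 9 rose in GMP-derived lines (median 0.32) and 2 in LT-HSC-derived lines at 72 h (0.25), and the smallest gap from their median to Hprt was 11.6 SD of those genes. A correction that moves genes of similar signal alike, as a normalization between arrays by signal does, is argued against as the whole cause. The median of genes within 0.5 log2 of the mean signal of Hprt lay at least 8.41 SD below it. Those medians were 0.01, 0.07 and 0.04 in the same 3 comparisons. Hprt was picked for its largest increase, and that choice by itself widens both gaps in SD. Quantile normalization and median centring left 99.07% or more of the effect. They moved no dox effect by more than 0.07 and so decide nothing. Other kinds of normalization stay open, since the method behind the deposited values is not given in the sources used here. Whether a dox-responsive promoter at the locus also drives its neighbours cannot be told apart: 91.54% of windows of 10 neighbouring genes moved as much as the one beside Hprt in GMP-derived lines, and 21.39% and 99.2% in LT-HSC-derived lines at 48 h and 72 h, but the bound written for that test was wrong, because only 1 of the 10 genes, Phf6, was above the median of all probe sets on most arrays. Phf6, named after its values were seen, was at 0.48 (adjusted p = 0.06), 0.70 (0.000128) and 0.57 (0.000185). Beyond the rise of purine genes and a promoter at the locus no biological explanation was tested.

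Dox called 88 genes in LT-HSC-derived lines at 48 h, against 1425 at 72 h and 2179 in GMP-derived lines. Fewer arrays as the whole cause are argued against: with the other comparisons reduced to 2 dox and 3 no-dox arrays, the lowest count was 859. Line B6-1, present at 48 h only without dox, is argued against as the whole cause, since the higher of the counts without that array and with the line as a replicate block was 295. Smaller effects at 48 h may contribute: over the genes called in GMP-derived lines, the median effect in that direction was at least 0.13 higher at 72 h in each of lines B6-2 (0.164 and 0.323) and B6-3 (0.155 and 0.286). Each such effect is the difference of 1 dox and 1 no-dox array. The direct test of 72 h against 48 h called 0 genes. Without dox, 36 genes differed between these times. Whether the dox or the no-dox cultures account for the larger effects at 72 h was not tested. The count of 88 was 12 and 10 without dox replicates 1 and 2, and 37 and 48 without no-dox replicates 2 and 3.

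As a list, ATF4 stress genes were higher with dox in LT-HSC-derived lines at 72 h and in GMP-derived lines, and at 48 h in LT-HSC-derived lines none of 19 passed over all genes and 1 rose adjusted over the list alone (camera, adjusted p = 0.000133, and adjusted p = 0.0646 with an estimated correlation). Whether a growth program shared with MYC and nucleolar genes contributes cannot be told. Over the 18 cultured arrays with group means removed, 10 biosynthesis and transport members correlated with the mean of the MYC and nucleolar list (mean r = 0.38, from -0.13 to 0.72). This passed the bound set beforehand, but other genes were not correlated with that mean for comparison. In GMP-derived lines 9 of these 10 members rose (median 0.58). Doxycycline itself, acting on mitochondria, stays open: the median of 7 stress regulators and effectors, of which 2 rose, was 0.22 there, and no dox-treated wild-type cells were measured. A biological effect of MLL-AF9 on these genes is confounded with dox in this design.

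Other splits of the same arrays were fitted for each comparison of groups of at least 3. For sorted GMP over sorted LT-HSC 1 of 35 splits, the real one, called as many genes (6402, highest other 3). The same held for GMP-derived lines over sorted GMP (1 of 35, 3943, highest other 3). It held for LT-HSC-derived lines over sorted LT-HSC as well (1 of 35, 6768, highest other 4727). The high values among the others in that case came from splits that were nearly the mirror of the real one. These shares lie under 0.05 but do not exclude chance, since 1 of 35 is the lowest share these splits can give. Other splits mix the groups compared, which widens the spread and lowers the count. Nothing says that the sorted replicates came from separate animals. Splits were too few for a share under 0.05 in the rest, where 1 split, the real one, called as many. These were dox in LT-HSC-derived lines at 72 h (1425, highest other 4 among 4 splits that part as many line pairs) and dox in GMP-derived lines (2179, highest other 445 among 8 such splits and 711 among all 35). In GMP-derived lines the other counts from 296 to 711 came from splits nearly the mirror of the real one, with 1 dox array in the group of 4. The remaining splits there called 12 genes or fewer. Further such comparisons were no-dox lines of both origins (1355, highest other 2 among 10 splits) and 72 h over 48 h (36, highest other 0 among 4 splits that part as many pairs and 26 among all 10).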

How the results depend on the processing

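The alternatives were planned, except that the spread without the array with the largest residual SD (LT-HSC-derived no-dox 72 h replicate 3) was chosen after seeing the data. Values of named genes called in the main fit or the alternative reversed in 0 cases, became weaker in 566 and stronger in 188. Values stayed on their side of the threshold in 11472 cases. A change of sign counted as unchanged where neither fit called the gene or list. For single lists these were 4448 unchanged, 200 weaker and 102 stronger. The number of arrays limits the precision. Signal over background was not analysed here.

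Requiring a 2-fold difference as well, which leaves fewer genes by construction, gave 1074 genes for sorted GMP over sorted LT-HSC, 44 for dox in LT-HSC-derived lines at 48 h, 207 at 72 h, 248 in GMP-derived lines, 124 and 209 between origins with and without dox, 1182 and 404 for LT-HSC-derived and GMP-derived lines over their sorted counterparts, 4 for 72 h over 48 h and 25 for the interaction of origin. Array weights gave 145 genes for dox in LT-HSC-derived lines at 48 h, 2241 at 72 h, 335 for 72 h over 48 h, 87 for the interaction of origin, 11 lists for the interaction of time and 75 shared lower genes. The cause was not tested. With only the groups compared, which leaves fewer arrays to estimate the spread, the counts were 54 and 647 for dox in LT-HSC-derived lines at 48 h and 72 h, 595 between origins without dox, 21 and 1 for the interactions of origin and time, and 7 shared higher genes. For 72 h over 48 h limma then called 0 genes, with an unadjusted p under 0.05 for 1823.

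With the line as a fixed replicate block the counts were 295 for dox in LT-HSC-derived lines at 48 h, 230 for 72 h over 48 h, 98 and 2 for the interactions of origin and time, and 42 and 200 shared genes, with a Pearson r of 0.635 and a Spearman rho of 0.359. The cause was not tested. Beyond the values given in the report, the block changed no call of a gene or list that the report gives. The consensus correlation within lines was 0.0524. Sorted replicates of different kinds share only a number. Lines of different origin carry the same line names, and whether those mark a shared donor is not given in the sources used here. In the comparisons between origins the block was that name. Across sorted cells the correlation of arrays with the same number was 0.06, 0.02, 0.03 and 0.05, and across origins it was 0.05 and 0.01 with dox and 0.02 and 0.17 without. Not every array correlated best with its own number or name.

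Median centring gave 21 genes for 72 h over 48 h, and the genes of sorted GMP moved by -0.065 with dox at 72 h without passing. Without the array with the largest residual SD the interaction of origin had 71 genes. The dim filter gave 9 lists for GMP-derived lines over sorted GMP, a median of 0.024 for the genes of sorted LT-HSC with dox at 72 h, a Pearson r of 0.628 and a Spearman rho of 0.442. Quantile normalization gave 8 lists for the interaction of time. With 50 genes per set the medians with dox at 72 h were 0.020 for genes of sorted LT-HSC and 0.033 for genes of sorted GMP, whose direction reversed. The cause was not tested.

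An estimated correlation left 6 lists for sorted GMP over sorted LT-HSC, 5, 5 and 7 for dox in LT-HSC-derived lines at 48 h and 72 h and in GMP-derived lines, 6 and 4 for the lines over their sorted counterparts and 2 for 72 h over 48 h. Between origins with and without dox camera then called 0 and 0 lists, and 0 for the interaction of time, with an unadjusted p under 0.05 for 5, 6 and 1 lists. It ended the calls of the genes of sorted GMP with dox in LT-HSC-derived lines at 48 h (-0.075) and 72 h (-0.075) and in GMP-derived lines (-0.114), and between origins with (-0.116) and without dox (-0.198). It ended those of the genes of sorted LT-HSC with dox at 72 h (0.023) and between origins without dox (0.083).

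Leaving out each array in turn gave ranges of 10 to 87 and 859 to 1329 genes for dox in LT-HSC-derived lines at 48 h and 72 h, 1224 to 2115 in GMP-derived lines, 110 to 355 and 743 to 1149 between origins with and without dox, 0 to 57 for 72 h over 48 h, and 8 to 55 and 0 to 2 for the interactions of origin and time. Lists ranged from 5 to 11 between origins with dox and from 3 to 9 for the interaction of time. Medians ranged from -0.039 to 0.008 and from -0.013 to 0.052 for genes of sorted LT-HSC with dox at 48 h and 72 h, and from -0.149 to -0.053 for genes of sorted GMP at 72 h. The Pearson r ranged from 0.491 to 0.611, the Spearman rho from 0.229 to 0.329, and shared genes from 4 to 25 higher and 4 to 49 lower. A random replicate block, the mean of probe sets and the prior with trend and robust settings moved no count of genes by over 1.5 times, and 500 genes per set left the 10 set results on their side of the threshold.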

Other observations

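The Hox clusters were looked at, and their arrays left out in turn, after the dox results were seen. Of 10 measured Hoxa genes 4 rose with dox in LT-HSC-derived lines at 48 h (Hoxa5, Hoxa6, Hoxa9 and Hoxa10) and 4 at 72 h, and 6 rose in GMP-derived lines, with Hoxa3 and Hoxa7 added. These counts were the same under quantile normalization and median centring, and the medians of the Hoxa genes were 0.49, 0.36 and 0.57. Without dox replicates 1 and 2 at 48 h in LT-HSC-derived lines 1 Hoxa gene, Hoxa9, was called in each fit (adjusted p = 0.187 and 0.3 for Hoxa5, 0.0816 and 0.141 for Hoxa6 and 0.0765 and 0.0671 for Hoxa10), and without no-dox replicates 1 and 2 there 3 were called, without Hoxa5 (adjusted p = 0.0985 and 0.089). With only the groups compared Hoxa5 did not pass at 48 h either (0.0619). Leaving out single arrays gave 4 or 5 at 72 h and 6 in GMP-derived lines. Of 9 genes each of Hoxb, Hoxc and Hoxd limma called 0 in each dox comparison, with unadjusted p under 0.05 for 0, 1 and 0 genes in LT-HSC-derived lines at 48 h, 1, 1 and 0 at 72 h and 0, 0 and 0 in GMP-derived lines. Under quantile normalization and under median centring 1 Hoxb gene was lower with dox at 72 h.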
